A study of Mus musculus with 10 samples.

How the data were processed

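Messenger RNA was measured in fully grown mouse oocytes, which are arrested at the germinal vesicle stage before meiotic maturation. Per the labels, each of the 10 samples held RNA of about 50 oocytes from 1 mouse, was labelled with biotin and was hybridised to 1 oligonucleotide array. The design text gives 4 samples from non-transgenic mice and 6 from mice whose transgene makes RNA interference against basonuclin in oocytes. Samples are named here by their group and the replicate number of their label, which are 1, 2, 7 and 8 for non-transgenic and 4, 5, 6, 11, 12 and 13 for RNAi-transgenic mice. The groups share no replicate number, which gives no pairs to use, so the samples were compared as unpaired.

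The authors deposited 1 expression intensity per probe set and array. Per the submitters' processing notes the tool was GCRMA, which corrects background by probe sequence, normalizes arrays to each other and summarises probes, with its version not given in the sources used here. The deposited intensity values were all above 0, on a linear scale and with near-equal quantiles across arrays, so they were put on the log2 scale without a new normalization. They carry no detection flag. GCRMA pulls dim probe sets toward a common floor, which makes their spread and their folds uncertain. The table held 45101 probe sets, of which 64 were array controls. The platform annotation gave 34958 probe sets 1 gene and 932 several genes, and 9211 were not listed in it and stay unnamed here. Of the probe sets with 1 gene, 34754 were found by gene number in the RefSeq table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other or share a chromosome. No genome build is named for the arrays, so no position is given.

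A probe set was tested where its log2 value was above 5, an intensity of 32, in at least 4 arrays, which left 18582. A gene was represented by its brightest probe set over all 10 arrays, which ignores the groups, so 10590 genes were tested. For 4036 of them more than 1 probe set passed the filter. Groups were compared with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Log2 fold changes are transgenic minus non-transgenic. Where every sample of the dimmer group was below log2 5, the fold is given as at least the brighter mean over that level. Where some but not all of its samples were below log2 5, the samples below it were set to that level, the fold is again given as at least that large, and the number of samples above the level stands beside it. Single values were compared by a two-sided exact permutation test over the 210 splits of the samples into 4 and 6, which cannot give a p below 0.00476. The fit was tested on 1 simulated data set with independent noise, in which 200 of 10590 genes were changed 1.5-fold, 2-fold or 4-fold. A small further set of genes with a smaller shift also counted as changed. The fit called 56.5% of genes changed 1.5-fold, 97.1% of those changed 2-fold and 98.4% of those changed 4-fold, and 7.14% of its calls were false. In the real data 37.2% of genes passed, a much larger part than was simulated, so these shares need not carry over. The number of arrays limits the precision.

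Gene lists were fixed before the data were examined, and cover transcription by RNA polymerases I, II and III, ribosomes, mitochondria, protein turnover, splicing, translation, oocyte and embryo genes, RNA interference, chromatin, stress, metabolism and markers of other ovarian and blood cells. The translation list was written as a name pattern and so also holds binding proteins and kinases of initiation factors. Of the 25 lists, 24 had at least 5 tested members and were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Named genes follow a rule fixed at the same time: both basonuclin genes, the 12 largest increases and 12 largest decreases among adjusted p below 0.05 without overlap between groups and with a mean log2 value above 7 in the higher group, and in each list up to 3 higher and 3 lower members by adjusted p, of which the text gives the first ones. The 3 most abundant markers of each other cell type are named whatever their p.

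Alternatives fixed beforehand were no filter, a level of 7, quantile normalization, median centring, log2(value + 16), eBayes without a trend, robust eBayes, array weights, the replicate number range as a covariate or as a subset, each sample left out, the mean of a gene's probe sets, each probe set by itself, and stricter thresholds. Alternatives added after seeing the data were each of 2 RNA length covariates, 5 settings with a threshold of 2-fold, and leaving out a pair of arrays that stood apart. Figures were drawn with matplotlib 3.10.9.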

Results

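Basonuclin (Bnc1) is a zinc finger protein found in keratinocytes of the skin and in germ cells, and is known to act at the genes of ribosomal RNA. The study lowered its mRNA in mouse oocytes by a transgene that makes RNA interference only there, and measured mRNA in 4 samples of non-transgenic and 6 samples of RNAi-transgenic fully grown oocytes, each of about 50 oocytes from 1 mouse. The median intensity of an array lay between 17.5 and 20.1, and between 40.1% and 40.9% of probe sets on each array were above the level used as a filter.

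Bnc1 mRNA was high in all non-transgenic samples and below the filter level in all transgenic samples. Its single probe set averaged an intensity of 3055 ± 327 (SD, n = 4) in non-transgenic and 14.6 ± 2.36 (SD, n = 6) in transgenic oocytes. On the log2 scale it fell from 11.57 ± 0.15 to 3.85 ± 0.21, at least 95.1-fold lower when set against the filter level. The highest transgenic sample was at log2 4.26 and the lowest non-transgenic sample at 11.40, so each sample matched its label. The difference was past the threshold in limma (adjusted p = 2.65e-11) and in the exact permutation test (p = 0.00476, the smallest the design allows). Whether the probe set overlaps the stretch targeted by the transgene is not given in the sources used here. Bnc2, the paralog of Bnc1, is also known from the germline and was abundant in both groups. Its brightest probe set was at log2 12.56 ± 0.10 in non-transgenic and 12.56 ± 0.11 in transgenic oocytes (exact permutation p = 0.967). A dimmer probe set was at 7.79 and 7.71 (exact permutation p = 0.586), and the third was below the filter, at 2.31 and 2.27.

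**Figure D1:**
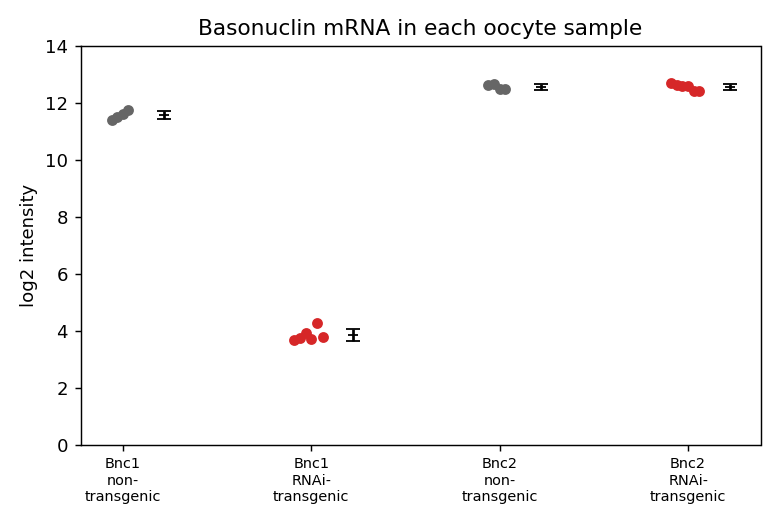
Log2 intensity of Bnc1 and of the brightest Bnc2 probe set in each sample, with 1 point per mouse and the mean ± SD beside the points. Bnc1 averaged 11.57 in the non-transgenic and 3.85 in the transgenic samples, and Bnc2 averaged 12.56 in both.

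Beyond Bnc1, a large part of the oocyte mRNA pool differed between the groups. Of 10590 genes tested, 3940 changed (37.2%): 1998 were higher and 1942 lower in transgenic oocytes, with 4869 at an unadjusted p below 0.05. After quantile normalization 1906 were higher and 2250 lower, and after centring each array on its median 1772 and 2441, so the direction with more genes turned with the scaling. At least 2-fold, 702 genes were higher and 249 lower (672 and 275 after quantile normalization, 664 and 285 after median centring). With values below the filter level set to that level, so that a size is a lower bound, 644 were higher and 235 lower at least 2-fold, and 81 were higher and 3 lower at least 8-fold. The genes that rose 2-fold had a median log2 level of 6.09 in non-transgenic and 8.35 in transgenic oocytes. Those that fell 2-fold went from a median of 8.30 to 6.95. Of the 702 genes, 114 were below the filter level in every non-transgenic sample, as against 11 of the 249 in the transgenic samples. The filter was unequal here. A gene below the level in all non-transgenic samples could pass it with only some transgenic samples above. A gene below the level in all transgenic samples had to be above it in every non-transgenic sample. Among all tested genes, 144 were of the first kind and 16 of the second. The filter can thus give part of this contrast, and no conclusion is drawn from it. Groups did not overlap for 28.0% of tested genes, where chance gives 0.952%. Within the samples numbered 1 to 6 alone, 1913 genes passed, and within those numbered 7 to 13, 2264 passed.

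**Figure D2:**
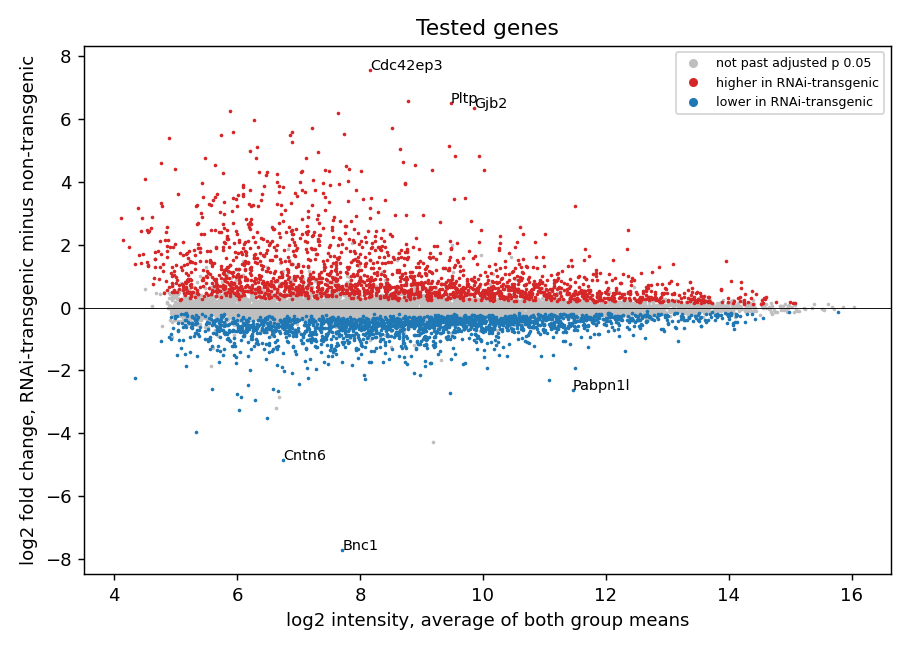
Each point is 1 tested gene, with its log2 intensity averaged over both group means on the x axis and its log2 fold change, transgenic minus non-transgenic, on the y axis. Red points (1998 genes) were higher and blue points (1942 genes) lower at an adjusted p of 0.05, and grey points did not pass.

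The largest fitted increase was in Cdc42ep3, which encodes an effector of the small GTPase Cdc42. It was at log2 11.95 ± 0.27 (SD, n = 6) in transgenic oocytes and above the filter level in only 1 of 4 non-transgenic samples, so the increase is given as at least 109.7-fold (limma adjusted p = 4.87e-08). Gjb2, which encodes the gap junction protein connexin 26, rose by 6.35 to log2 13.03, and the phospholipid transfer protein gene Pltp rose by 6.50 to 12.73. Tktl1, related to transketolase, was at log2 12.07 in transgenic oocytes and above the filter level in 3 of 4 non-transgenic samples, at least 90.1-fold higher. Tnfrsf19 of the tumour necrosis factor receptor family rose by 5.71. The galectin gene Lgals3 was at least 52.3-fold, the keratin gene Krt79 at least 29.4-fold and the sphingomyelin synthase gene Sgms2 at least 20.6-fold higher, each above the filter level in 1 of 4 non-transgenic samples. The transporter-like gene Mfsd4a, above it in 2 of 4, was at least 44.1-fold higher. Tulp2, Phldb2 and Fxyd6 were below the filter level in every non-transgenic sample and were at least 16.2-fold, 19.2-fold and 13.3-fold higher in transgenic oocytes. These 12 genes were higher in 6 of 6 transgenic samples than in any non-transgenic sample, as the rule for naming them requires.

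After Bnc1, the largest fitted decrease was in Cntn6, a neural adhesion molecule. It was at log2 9.17 ± 0.24 (SD, n = 4) in non-transgenic oocytes and above the filter level in only 1 of 6 transgenic samples, at least 17.99-fold lower (limma adjusted p = 1.65e-08). Plxdc2 and Tub were below the filter level in every transgenic sample, at least 4.93-fold and 6.36-fold lower. Tmem74, above the level in 1 of 6 transgenic samples, was at least 9.19-fold lower, Fam47e (4 of 6) at least 5.58-fold, Bpifc (2 of 6) at least 5.14-fold and Rbm12b1 (3 of 6) at least 4.86-fold lower. Cyp20a1 and Hdac9, a histone deacetylase, were each above it in 5 of 6, at least 5.91-fold and 5.83-fold lower. Cdh2, which encodes N-cadherin, changed by -2.72 and stayed at log2 8.11 in transgenic oocytes. Pabpn1l, an oocyte form of the nuclear poly(A)-binding protein, was abundant in non-transgenic oocytes at 12.78 ± 0.30 and changed by -2.63 to 10.15 ± 0.62.

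Genes of the transcription and ribosome machinery were examined because basonuclin is known to act on ribosomal RNA genes. For RNA polymerase I, its factors and ribosome assembly, 4 of 40 tested members rose and 12 fell (4 and 12 adjusted over the list alone). Rrn3, which recruits polymerase I to its promoter, changed by -0.83 (SE 0.09) and Taf1a of the selectivity factor by -0.61, while Znrd1, a polymerase I subunit, changed by 0.60 and Nhp2 by 0.67. The list as a whole did not pass against other genes (camera adjusted p = 0.304). For RNA polymerase II and general factors, 8 of 49 rose and 10 fell (8 and 10 adjusted over the list alone), with Gtf2b at 0.81 and Polr2j at -0.47 (camera adjusted p = 0.789). For RNA polymerase III, 2 of 22 rose and 5 fell (3 and 6 adjusted over the list alone), with Polr3c at -0.92, Polr3b at -0.90 and Snapc1 at 0.53 (camera adjusted p = 0.304). Fry, which does not compare a list with other genes, put the polymerase I and III lists lower (fry adjusted p = 0.0276 and 0.0143). The polymerase II list did not pass there (fry adjusted p = 0.531).

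Among cytosolic ribosomal proteins, 4 of 42 rose and 13 fell (4 and 14 adjusted over the list alone), with Rplp0 at 0.38 and Rps18 at -0.34 (camera adjusted p = 0.142). Among mitochondrial ribosomal proteins, 7 of 75 rose and 22 fell (7 and 23 adjusted over the list alone), with Mrpl39 at -0.94, Mrpl40 at -0.68 and Mrps10 at 0.94 (camera adjusted p = 0.0785, and adjusted p = 0.768 with an estimated correlation). With the preset correlation this list passed without non-transgenic replicate 8 (adjusted p = 0.0288), without transgenic replicate 4 (adjusted p = 0.0335) and with the Gapdh difference of each sample as a covariate (adjusted p = 0.0229). Of the nuclear genes of the respiratory chain, 7 of 76 rose and 14 fell (6 and 13 adjusted over the list alone), with Atp5g3 at 0.99 and Atp5o at -0.60 (camera adjusted p = 0.477). Proteasome subunits gave 2 higher and 4 lower of 35 (2 and 4 adjusted over the list alone), with Psmb3 at 0.88 and Psmd10 at -0.51 (camera adjusted p = 0.629). Splicing factors gave 6 higher and 7 lower of 64 (5 and 4 adjusted over the list alone), with Lsm8 at 1.05 and Lsm6 at -0.39 (camera unadjusted p = 0.76). Translation factors gave 6 higher and 6 lower of 50 (6 and 6 adjusted over the list alone), with Eif4ebp1, an inhibitor of cap-dependent translation, at 0.91 and Eif3f at -0.55 (camera adjusted p = 0.952). The median of the translation list was 0.01 while its camera test pointed down, and the mean of the splicing list was 0.01 while its median was -0.03.

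Of 34 genes of growing oocytes, 2 rose, 5 fell and 27 did not pass (2 and 5 adjusted over the list alone, camera adjusted p = 0.774). The receptor gene Kit rose by 0.78 and Astl, which encodes ovastacin, by 0.53, while Oosp3 changed by -0.48 and the oocyte homeobox gene Lhx8 by -0.28. Of 41 genes with a maternal requirement in early development, 5 rose and 12 fell (6 and 12 adjusted over the list alone, camera adjusted p = 0.304). Zfp36l2, which promotes mRNA decay, rose by 1.92, and the trophectoderm factor Cdx2, above the filter level in 1 of 4 non-transgenic samples, was at least 3.31-fold higher, while Trim24 changed by -0.79 and Nlrp4a by -0.34. Of 49 meiotic and cell cycle genes, 10 rose and 9 fell (10 and 9 adjusted over the list alone, camera adjusted p = 0.749), with the cyclin gene Ccna2 at 0.52, the kinase gene Aurkc at 1.00, the cohesin gene Smc1b at -0.50 and Birc5 at -0.19. Of 49 genes of mRNA storage and decay, 3 rose and 7 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.463). Igf2bp3, an mRNA-binding protein, changed by -1.48, and Cpeb2, below the filter level in all non-transgenic samples, was at least 1.66-fold higher. Of the 4 genes known from the 2-cell stage that were tested, Usp17la changed by 2.09 and Obox3 by -0.35 (1 and 1 adjusted over the list alone), and 4 members are too few for a list test. Obox3 lost its call without non-transgenic replicate 2 (adjusted p = 0.0573).

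The transgene makes RNA that enters RNA interference, and the genes of that pathway and of the response to foreign RNA were followed for this reason. Of 26 genes of RNA interference, 4 rose and 2 fell (3 and 2 adjusted over the list alone, camera adjusted p = 0.771). Piwil4, a PIWI protein of the male germline, was below the filter level in every non-transgenic sample and at least 13.6-fold higher in transgenic oocytes, Tnrc6b changed by 0.65 and Drosha by -0.30. Of 15 tested interferon response genes, 2 rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.771). The RNA sensor genes Ddx58 and Tlr3 changed by -1.45 and -1.39, and Irf1 by 0.34. Of 67 genes of DNA methylation and histone modification, 8 rose and 12 fell (6 and 11 adjusted over the list alone, camera adjusted p = 0.716). Tet1, which oxidises methylcytosine, was above the filter level in 3 of 4 non-transgenic samples and at log2 9.61 ± 0.13 (SD, n = 6) in transgenic oocytes, at least 20.2-fold higher, and the arginine methyltransferase gene Prmt5 rose by 1.30, while Dnmt3b changed by -0.59 and Atrx by -0.58. The mean of this list was 0.01 and its median -0.04.

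The list of p53 response and apoptosis was the only one of the 24 lists tested to pass. Of its 29 tested members 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a median change of 0.25 (camera adjusted p = 0.0341). This call was lost with an estimated correlation (adjusted p = 0.396 with an estimated correlation). Sesn1, a stress-induced regulator of growth, rose by 1.99 (SE 0.13), Perp, a membrane protein of epithelia, by 1.64 and the BCL2-family member Bik by 1.57, while Casp2 changed by -0.32. Casp2 lost its call when any 1 of non-transgenic replicates 2, 7 and 8 or of transgenic replicates 4, 5, 6, 11 and 13 was left out, with adjusted p from 0.052 to 0.104. The list also lost its call without non-transgenic replicate 7 (adjusted p = 0.0573) and without transgenic replicate 13 (adjusted p = 0.0623). Further losses came with the stricter filter (camera adjusted p = 0.123), quantile normalization (0.0658) and median centring (0.0655). The call was lost too within samples 1 to 6 (camera adjusted p = 0.0628) and without the pair of arrays that stood apart (0.0559).

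Of 37 chaperones, 3 rose and 12 fell (3 and 12 adjusted over the list alone, camera adjusted p = 0.142). The heat shock gene Hspa1a rose by 1.77 and Dnajb9 by 1.43, while Canx changed by -0.42 and Cct5 by -0.35. Of 87 genes of the cytoskeleton, 20 rose and 15 fell (20 and 16 adjusted over the list alone, camera adjusted p = 0.789), with the tubulin gene Tuba1a at 4.84, the kinesin gene Kif26b at 3.03 and Kif24 at -1.15. The myosin gene Myo1a, above the filter level in 2 of 4 non-transgenic samples, was at least 14.6-fold higher. Of 22 genes of cholesterol synthesis, 7 rose and 2 fell (7 and 2 adjusted over the list alone, camera adjusted p = 0.304), with Tm7sf2 at 2.55, Ebp at 1.85 and Fdft1, the squalene synthase gene, at -0.50. Of 205 zinc finger genes named Zfp, 22 rose and 65 fell (22 and 67 adjusted over the list alone, camera adjusted p = 0.0785), with Zfp653 at -1.05 and Zfp141 at least 3.71-fold lower. Zfp819, above the filter level in 1 of 4 non-transgenic samples, was at least 22.3-fold higher.

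**Figure D3:**
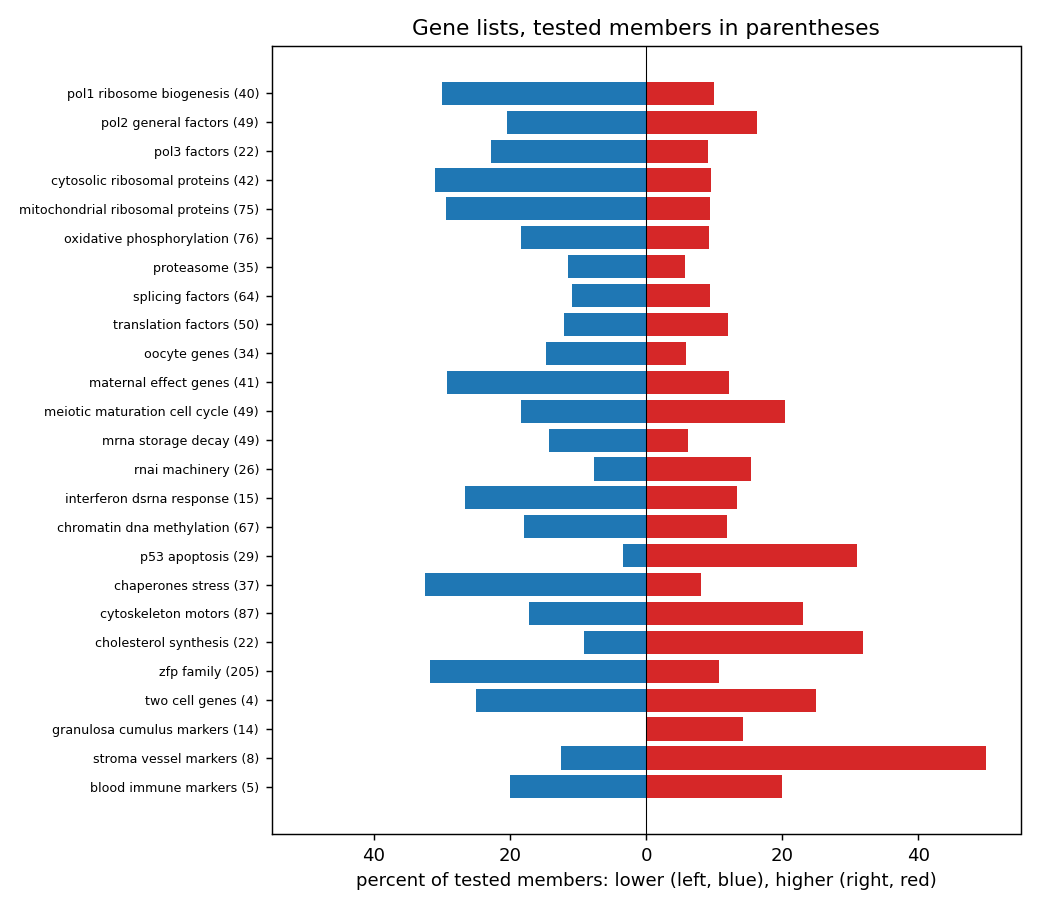
Percent of the tested members of each fixed gene list that were higher (red, right) or lower (blue, left) in transgenic oocytes at an adjusted p of 0.05, with the number tested in parentheses. The p53 and apoptosis list had 31.0% higher and 3.45% lower members.

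None of the lists of markers of other cells passed against other genes. Of 14 tested markers of granulosa and cumulus cells, which surround the oocyte, 2 rose and 0 fell in limma, with 0 lower also adjusted over the list alone (2 higher) and a camera adjusted p of 0.463. The most abundant were Nr5a2 at log2 9.94 and 9.87 in non-transgenic and transgenic oocytes, Gja1 at 8.01 and 8.56 and Gata4 at 7.98 and 7.61, of which none passed, except Gata4 without non-transgenic replicate 7 (adjusted p = 0.0387). Fshr rose by 1.24 to 6.75. Cyp11a1, above the filter level in 3 of 4 non-transgenic samples, was at least 2.95-fold higher at 7.07, and lost its call without non-transgenic replicate 8 (adjusted p = 0.0682). Of 8 tested markers of stroma and vessels, 4 rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.142). Kdr rose by 1.19, Col4a2 by 1.13 and Postn by 0.81, Dcn, above the level in 3 of 4 non-transgenic samples, was at least 2.15-fold higher, Acta2 changed by -0.50, and Col4a1 was at 7.86 and 7.80. Of 5 blood and immune markers, 1 rose and 1 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.923). Laptm5 rose by 1.06 and Srgn, the brightest of them, changed by -0.56 from log2 11.27 to 10.71, while H2-Aa was at 9.40 ± 0.77 and 9.73 ± 0.93. Acta2 lost its call without any 1 of non-transgenic replicates 1 and 8 or of transgenic replicates 4, 5, 11, 12 and 13 (adjusted p from 0.0597 to 0.104), and Laptm5 without non-transgenic replicate 2, 7 or 8 (0.0571 to 0.0691). The median of the blood and immune list was 0.08 while its camera test pointed down.

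The samples separated by genotype. The first principal component held 67.6% of the variance over the tested genes and 99.8% of it lay between the groups (exact permutation p = 0.00476). The second held 8.10%, of which 52.7% lay between the replicate number ranges (exact permutation p = 0.00794, the smallest that these ranges allow), which no label calls batches. Pairs of arrays correlated with a median r of 0.984 within non-transgenic, 0.988 within transgenic and 0.944 between groups, across genes, which are not independent replicates. No 2 arrays held identical values.

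RNA length was compared through the 3' and 5' control probe sets. The Actb difference, 3' minus 5' on the log2 scale, was 3.74 ± 0.23 (SD, n = 4) in non-transgenic and 3.94 ± 0.61 (SD, n = 6) in transgenic samples (exact permutation p = 0.714), with transgenic replicate 6 at 5.13. The Gapdh difference was 4.05 ± 0.26 and 3.77 ± 0.18 (exact permutation p = 0.114). For both controls the 3' probe set was much brighter than the 5' one in every sample, by at least 3.40 (Actb in transgenic replicate 12). Without transgenic replicate 6 the Gapdh difference between the groups was -0.35, and without non-transgenic replicate 2 it was -0.39, both past an exact permutation p of 0.05. With the Gapdh difference of each sample as a covariate, Casp2 (adjusted p = 0.114), Obox3 (0.0584), Cyp11a1 (0.119) and Acta2 (0.325) lost their calls.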

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

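In this part the tests for somatic cells, for a strain segment and within the number ranges were written after the values had been seen, and the Actb and Gapdh covariates and the added settings at 2-fold were chosen after seeing the data.

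The count of changed genes is the first pattern: among 100 of the 210 splits of the samples into 4 and 6, only 1, the real one, gave as many (3940, where the highest of the others gave 2). That is the smallest share that 100 splits can give. The group difference itself widens the error in splits that mix the groups and lowers their counts. Their counts therefore do not measure how many genes would pass by chance. With the Actb difference of each sample as a covariate, 94.7% of the changed genes stayed past the threshold in the same direction. This difference hardly differed between the groups (exact permutation p = 0.714), so as a covariate it could take little from the group difference, and no conclusion is drawn from it. With the Gapdh difference 74.2% stayed (95.5% of those changed 2-fold), so RNA length as the Gapdh control measures it does not account for most of the count. For the 1017 genes lost with the Gapdh difference the median size went from 0.41 to 0.36 on the log2 scale and its median SE from 0.12 to 0.15, so both a smaller size and a wider error ended their calls, and RNA length stays open there. Both number ranges hold the groups in equal shares, so a shift between the ranges that is equal in both groups cannot make a group difference. Within samples 1 to 6 alone 46.2% of the changed genes passed in the same direction and within samples 7 to 13 alone 53.4%. These subsets are of the arrays that gave the calls, so these shares do not test such a shift. Within each range the non-transgenic samples have the lower numbers, so anything that follows the numbers there cannot be told from the group. A mouse line or litter difference that goes with the transgene cannot be separated from basonuclin loss in this design and was not tested.

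The second pattern is that 702 genes rose at least 2-fold while 249 fell. With log2(value + 16), which damps folds from dim values, the ratio of higher to lower genes was 3.23, after quantile normalization 2.44, after median centring 2.33 and with values below the filter level set to it 2.74, so neither the floor nor the scaling removed it. Somatic cells carried along would bring their abundant transcripts, of which 33 were on the array and 20 were tested. These 20 had a median log2 change of 0.099 (quartiles -0.04 and 0.33). Of them 2 fell (Ppib by 0.91 and Igfbp7 by 0.62) and 5 rose (Ahnak by 2.00, B2m by 0.87, Itm2b by 0.85, Psap by 0.36 and Anxa5 by 0.31). Psap lost its call without any 1 of 7 samples, Anxa5 without non-transgenic replicate 1 or 2, and B2m, Psap and Anxa5 with the Gapdh covariate. Psap also lost it without a filter, after quantile normalization and after median centring (limma adjusted p from 0.0592 to 0.0776). The number range as a covariate, each probe set by itself and omission of both arrays that stood apart ended it too (0.0520 to 0.0546). Of the 9 tested at log2 8 or less in non-transgenic oocytes, where the oocyte's own level hides less, 1 rose (median 0.14, quartiles -0.03 and 0.25). The 13 not tested had means below the filter level in both groups, of which Vim was the brightest in non-transgenic oocytes (4.34, and 4.19 in transgenic ones). Over all 33 the median log2 change was 0.0072. Of 24 stroma and vessel markers on the array 8 were tested, of which 4 rose and 1 fell (median 0.47, camera adjusted p = 0.142). Without a filter, which adds the dim members, the median of that list was -0.0019. The values argue against somatic cells for most of the pattern and leave a small share of stroma or vessel cells open. A response to basonuclin loss stays a hypothesis.

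The third pattern is the 2-fold changes as a whole, set against a segment of another strain carried with the transgene. Such a segment lies on 1 chromosome, and the chromosome with the highest share held 9.28% of these genes and 7.85% of the tested ones. A single segment's own genes can thus make up at most 9.28%. No chromosome held more than 8.04% of the tested genes, so this outcome was nearly fixed beforehand, and a smaller part stays open. Among 20 neighbouring tested genes at most 9 changed 2-fold, where shuffled genes gave a median of 7 and a 95th percentile of 9. Effects of such a segment on genes elsewhere, and of several segments, were not tested.

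Samples stood apart from the rest of their group in 23 of 284 sets of values, where chance gives about 1 in 20. Transgenic replicate 6 was far above its group in the Actb 3' minus 5' difference (5.13) and the Gapdh difference (4.12), in Lsm8 (9.07) and in Hspa1a (10.59), and below it in Rrn3 (9.14). Among the other transgenic samples, Krt79 in replicate 13 (10.72), Mrps10 in replicate 4 (7.81), Tm7sf2 in replicate 11 (9.11) and Twnk in replicate 12 (5.51) were high, and Ddx58 in replicate 4 (7.37), Cyp11a1 in replicate 11 (5.18) and Col4a1 in replicate 5 (7.33) were low. Among non-transgenic samples, replicate 1 was low in Lhx8 (14.22), Irf1 (10.42) and Ssbp1 (11.98). Replicate 2 was low in Zfp36l2 (6.18), Tlr3 (6.53) and Ebf2 (4.59), and high in Pkp2 (9.01). Replicate 7 was high in Casp2 (9.06) and Col4a2 (7.00), and replicate 8 in Col4a1 (8.19) and Id3 (5.22). All these are log2 values.

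Probe sets without a single named gene were outside the comparison by gene. Of 1775 such probe sets above the filter, 231 were higher and 241 lower in transgenic oocytes.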

How the results depend on the processing

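The count at 5 settings with a 2-fold threshold, the Actb and Gapdh covariates and the omission of both arrays that stood apart (non-transgenic replicate 1, farthest out on the second component, and transgenic replicate 6, highest in the Actb difference) were chosen after seeing the data. Bnc1 stayed lower and past the threshold in every alternative run, and the first component kept its split between the groups. The fitted log2 changes of Bnc1 lay between -7.80 and -6.65, and their exact size is uncertain because its transgenic values were below the filter level. Of 139 named genes, 98 kept direction and side in all of their alternatives, and 13 lost a call outside the number ranges: Casp2, Acta2, Cyp11a1, Laptm5, Obox3, Krt12, Fzd3, Armc1, Psap, Anxa5, B2m, Exosc8 and Ywhag. With the Gapdh covariate all of these but Laptm5, Fzd3 and Armc1 lost it (adjusted p from 0.0584 to 0.325). Over all named genes 114 values lost a call, 50 of them within a number range, where fewer samples were tested, and 1 gained a call. Of all 3940 changed genes, 5 passed in the opposite direction in an alternative, with the mean of a gene's probe sets, and are named here after their values were seen. They were Exosc8 (0.23, then -0.81), Cntd1 (-0.40, then 0.27), Ywhag (-0.38, then 0.33), Fzd3 (0.59, then -0.58) and Armc1 (0.32, then -0.58). With each probe set by itself, a gene was followed only through its brightest probe set, so this setting could not add to the 5. Of 986 genes with at least 2 changed probe sets, 58 had probe sets that changed in opposite directions. Fzd3 lost its call without non-transgenic replicate 7 (adjusted p = 0.0531), and Armc1 without non-transgenic replicate 2 or 7 or transgenic replicate 12 or 13 (adjusted p from 0.0527 to 0.0913).

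Changed genes numbered 3383 to 3772 when 1 sample was left out. Within samples numbered 1 to 6 there were 1913 (1207 higher, 706 lower) and within those numbered 7 to 13 there were 2264 (1241 and 1023), with fewer samples in each fit. Every probe set by itself gave 6162 (3156 and 3006), because more features were tested. Stricter thresholds gave fewer by construction: 2501 at an adjusted p of 0.01 (1102 lower), 2024 at 1.5-fold (1231 and 793) and 951 at 2-fold (702 and 249). At 2-fold there were 799 (610 and 189) with log2(value + 16), 947 (672 and 275) after quantile normalization, 949 (664 and 285) after median centring, 879 (644 and 235) with values below log2 5 set to 5 and 971 (709 and 262) without a filter. GCRMA's floor limits the values of dim genes.

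The number of lists past camera was 1, and 0 under the stricter filter, quantile normalization, median centring, samples 1 to 6, both arrays left out and an estimated correlation. It was 2 with the Gapdh covariate. It lay between 0 and 2 when 1 sample was left out, and fry, which does not compare a list with other genes, gave 10. The cause was not tested. Fry put polymerase I, polymerase III, mitochondrial ribosomal proteins, mRNA storage and decay, chaperones and Zfp genes lower (fry adjusted p from 0.00083 to 0.0276). Higher with fry were p53 and apoptosis, the cytoskeleton, cholesterol synthesis and stroma and vessel markers (fry adjusted p from 0.000105 to 0.0143). List medians changed sign, with no call on either side. Without a filter, which adds the members that it had left out, the medians of granulosa and stroma markers went from 0.38 and 0.47 to -0.027 and -0.0019. The medians of the other lists named here lay between -0.04 and 0.10 with the filter. Without it they were -0.0039 for translation factors, -0.030 for the cytoskeleton and -0.029 for blood markers. The stricter filter gave 0.0058 for oocyte genes and -0.0035 for RNA interference. Quantile normalization gave -0.0031 for translation, -0.031 for RNA interference, -0.016 for the cytoskeleton and -0.012 for blood markers. Median centring gave -0.044 for translation, -0.024 for meiosis, -0.045 for RNA interference and -0.055 for the cytoskeleton. Array weights gave -0.047 for the cytoskeleton. Samples 1 to 6 gave 0.0082 for polymerase II, -0.036 for translation, 0.0045 for oocyte genes, -0.072 for RNA interference, 0.021 for interferon and -0.042 for the cytoskeleton, and samples 7 to 13 gave -0.035 for RNA interference. The mean of probe sets gave 0.021 for interferon and -0.027 for the cytoskeleton. The Actb covariate gave 0.0043 for polymerase II and -0.045 for the cytoskeleton, the Gapdh covariate -0.020 for translation, 0.021 for oocyte genes, 0.056 for interferon, -0.0062 for the cytoskeleton and -0.022 for cholesterol synthesis, and omission of both arrays -0.022 for RNA interference and -0.045 for the cytoskeleton. Leaving out 1 sample gave ranges of -0.056 to 0.0077 for the cytoskeleton, -0.085 to 0.021 for interferon, -0.069 to 0.019 for oocyte genes, -0.053 to 0.010 for polymerase II, -0.012 to 0.053 for RNA interference, -0.051 to 0.0080 for splicing and -0.0050 to 0.020 for translation.

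Bnc2, which never passed, was at 0.010 after quantile normalization, 0.0018 with array weights, 0.0029 within samples 7 to 13, 0.015 without both arrays, and -0.031 to 0.028 when 1 sample was left out. H2-Aa was at -0.0015 within samples 7 to 13, and Col4a1 at 0.096 with the Gapdh covariate and -0.11 to 0.046 when 1 sample was left out. The group difference of the Actb control lay between -0.035 and 0.31, below 0 without transgenic replicate 6, and that of the Gapdh control between -0.39 and -0.18, past the threshold without transgenic replicate 6 (-0.35) or non-transgenic replicate 2. The cause was not tested.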

Other observations

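The gene families in the first paragraphs were written after the changed genes had been seen, and their p-values are not independent evidence. A gene below the filter level in all 4 non-transgenic samples was tested only if transgenic samples were above it. Such members favour rises in the counts and in camera. The array held 245 developmental transcription factors, 44 keratins, 73 junction and envelope genes and 35 immediate early genes, more than were tested. The families were not tested without the filter. Of 20 tested immediate early genes and targets of MAP kinase signalling, 12 rose and 0 fell in limma (camera adjusted p = 1.37e-06 over 7 families). The phosphatase gene Dusp1 rose by 2.47 and Klf4 by 2.96, and Fos, above the filter level in 1 of 4 non-transgenic samples, was at least 10.2-fold higher. Of 9 targets of BMP and TGF-beta signalling, 7 rose, with Id2 at 3.08, Id3 (above the filter level in 1 of 4 non-transgenic samples) at least 8.32-fold and Tgif1 at least 4.85-fold higher (camera adjusted p = 4.41e-05). Of 71 developmental transcription factors, 32 rose and 9 fell (camera adjusted p = 4.27e-05), with Foxn4 at 3.26, Dmrtb1 at -1.72 and Ebf2, above the filter level in 3 of 4 non-transgenic samples, at least 15.7-fold higher. Of 19 keratins, 10 rose and 1 fell (camera adjusted p = 0.000706), with Krt73 at 2.84 and Krt12 at -0.19, which lost its call when non-transgenic replicate 2 or 7 or transgenic replicate 5, 11, 12 or 13 was left out (adjusted p from 0.0502 to 0.0875) and with the Gapdh difference as a covariate (adjusted p = 0.0863). Of 40 epithelial junction and cornified envelope genes, 17 rose and 2 fell (camera adjusted p = 4.27e-05), with Elf3 at 4.63, Tgm1 at least 4.16-fold higher and Pkp2 at -0.84.

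Of 23 genes of glycolysis and the hypoxia response, 13 rose and 4 fell (camera adjusted p = 0.00153), with the hexokinase gene Hk2 at 3.46 and Tpi1 at -1.55. The metallothionein genes Mt4 and Mt2 rose by 4.83 and 2.90, Mt1 was at least 8.20-fold higher, and 4 tested members are too few for a list test. Of 15 tested genes that replicate and transcribe mitochondrial DNA, 2 rose, 6 fell and 7 did not pass. Their camera adjusted p was 0.0358, and the call was lost with an estimated correlation (adjusted p = 0.182 with an estimated correlation). The mitochondrial RNA polymerase gene Polrmt changed by -1.91, Tfam by -1.06 and Ssbp1 by 0.71, and the helicase gene Twnk, above the filter level in 1 of 6 transgenic samples, was at least 2.80-fold lower. With an estimated correlation the other 6 families that could be tested kept an adjusted p between 0.00372 and 0.0145.

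Neighbouring genes changed together more often than shuffled genes. In 76 pairs of neighbouring tested genes both changed at least 2-fold in the same direction, where 1000 shuffles gave a median of 52 and a 95th percentile of 64 (permutation p = 0.001, the smallest they can give). Leaving out pairs whose symbols share their first 3 letters, as gene families do, left 66 pairs against a 95th percentile of 62 (permutation p = 0.014). Shared regulation of neighbouring genes may therefore account for some pairs, as a hypothesis. A strain segment carried with the transgene was not told apart from it.

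The array controls for 18S ribosomal RNA did not pass. The arrays were normalized to each other and served to measure mRNA, so these values do not show whether the amount of ribosomal RNA differed. The 5' probe set was at log2 12.77 ± 0.51 and 12.23 ± 0.44 (exact permutation p = 0.1), the middle one at 12.26 and 11.95 (exact permutation p = 0.348) and the 3' one at 9.16 and 9.22 (exact permutation p = 0.848). Of 986 genes with at least 2 changed probe sets, 58 had probe sets that changed in opposite directions.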
